A study of Homo sapiens with 4 samples.

How the data were processed

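Gene expression was measured in QGP-1 cells, an established human pancreatic neuroendocrine tumour line, on 4 one-colour microarrays. Per the labels' protocols, total RNA was purified on NucleoSpin columns, amplified with an amino allyl MessageAmp II kit and labelled with Cy5. The values deposited by the authors are linear probe intensities, whole numbers for 28264 probes on each array. Some intensities were below 0, which shows that a background had been subtracted. The scanner, the extraction software and any scaling between arrays were not given in the sources used here. No genome build was named either, so genes carry no coordinates here.

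The arrays fell into 2 groups of 2 by their labels, mock and stellate cell medium (PSC medium). The labels do not say whether the arrays of a group came from separate cultures, so p-values of genes measure only the spread between these samples, which may be technical. Arrays of a group were not copies of one another: 121 of 28264 probes held identical values in the mock pair and 105 in the PSC medium pair. The number of arrays limits the precision, with 2 residual degrees of freedom per gene.

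The median intensity of the arrays differed by 0.325 on the log2 scale, above the limit of 0.2 set for treating them as already normalized. The linear intensities were therefore quantile normalized, given a floor of 1 and log2 transformed. Fold changes of dim genes depend on this floor, since 160 genes had a floor value on at least 1 array. Gene symbols came from the platform's probe table and were updated through Entrez IDs with the RefSeq table of GRCh38.p14. All 25893 named probes matched, no symbol changed, no probe had several genes, and 2371 probes had none. Each gene was represented by its brightest probe over the 4 arrays, which gave 19090 genes, 5751 of them with more than 1 probe.

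Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over the 19090 genes and a threshold of 0.05. The moderated fit had 3.97 prior degrees of freedom and a median standard error of 0.178. Unless another setting is named, every adjusted p of a gene is from this limma fit. Fold changes are PSC medium minus mock on the normalized log2 scale, and levels are means ± SD of normalized log2 intensities. Gene lists were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over 30 lists. This test sets a list's genes against all other genes, so its p-values rest on the spread across genes. They do not measure replication between arrays, however small they are. Listed genes not analysed here numbered 51. Each list's count was also taken with p adjusted over the list alone, and each list was tested again with an estimated correlation. With an estimated correlation camera takes the 2 residual degrees of freedom of the arrays, so few lists can pass.

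The groups, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took genes past the threshold whose groups did not overlap and whose mean in at least 1 group lay above the median gene level of 10.13. From these it took the 15 with the largest positive and the 15 with the largest negative change. It added up to 4 members of each list by smallest p, and any leading member needed to say that it did not pass. Genes named outside the rule are identified where they appear as chosen after their values were seen. Alternatives covered normalization, dim genes, an added constant of 50, the probe of a gene, the variance model, the threshold, the replicate number as a block, each array left out, and the set test. Leaving out genes with a floor value, alone or with another variance prior, and leaving out list members shared with the ATF4 list were chosen after seeing the data.

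The procedure was tested on simulated data for the 19090 genes. Changed genes were drawn only from above the 25th percentile of level, so recovery was not tested for dimmer ones. Noise was drawn with each gene's moderated SD from the main fit. Simulated arrays did not differ in scale or background as the real ones did, so the rates below do not test the normalization. With 100 genes changed by 1 on the log2 scale and 100 by 2, the procedure recovered 52% and 99%, none with the wrong sign. It also called 19 of 18890 unchanged genes, which was 11.2% of 170 calls and more than the threshold of 0.05 allows for. Of these 19 false calls, 16 lay under the 25th percentile of level. In simulated lists, camera at the preset correlation called the 1 list of 40 genes shifted by 0.8 and 0 of 30 unshifted lists, and with an estimated correlation it called 0 of 1. Simulated genes varied independently, while estimated correlations of the real lists reached 0.23. The 0 of 30 thus does not test false calls in lists of correlated genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.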

Results

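Gene expression was compared between QGP-1 cells exposed to medium conditioned by pancreatic stellate cells and mock-treated QGP-1 cells. QGP-1 is a line from a human pancreatic neuroendocrine tumour, and stellate cells are the matrix-producing mesenchymal cells of the pancreas. The cells, grown in RPMI-1640 with 10% fetal bovine serum, were kept for 24 h at 0.1% serum in either condition. Each condition was measured on 2 arrays of 28264 probes. Summed intensity was 135782105 and 173359996 on mock arrays 1 and 2, and 167204563 and 161573995 on PSC medium arrays 1 and 2. Median intensity was 662, 829, 800 and 822 in the same order. Across genes of the normalized arrays, which are not independent replicates, Pearson's r was 0.986 within the mock pair, 0.988 within the PSC medium pair and 0.978 to 0.981 between groups. SST, the gene of the hormone somatostatin, had a level of 18.32 ± 0.19 in mock cells (SD, n = 2).

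The comparison asks how gene expression of QGP-1 cells differs with and without medium conditioned by stellate cells. Whether the mock medium had been conditioned without cells was not given in the sources used here, so released factors and depleted nutrients are not set apart by any value. The calcium-binding protein gene S100A2 rose 7.48-fold with PSC medium, from 13.28 ± 0.12 to 16.18 ± 0.02 (SD, n = 2 per group; log2 fold change 2.90 ± 0.16 SE, adjusted p = 0.00885). INHBA, which encodes the subunit of activin A, rose 6.64-fold (2.73 ± 0.17, adjusted p = 0.00946), and the interstitial collagenase gene MMP1 rose 5.87-fold (2.55 ± 0.22, adjusted p = 0.0131). FST, which encodes the activin-binding protein follistatin, fell from 17.66 ± 0.26 to 15.45 ± 0.02 (-2.20 ± 0.19, adjusted p = 0.0122). BLM, a RecQ helicase gene, fell from 11.96 ± 0.37 to 9.70 ± 0.03 (-2.26 ± 0.21, adjusted p = 0.0152).

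In all, 223 genes rose and 186 fell among 19090, which was 2.14% of the genes, and 205 and 163 of them changed at least 2-fold. The groups did not overlap for 53.5% of all genes. The mean over the 3 possible splits of the arrays is 33.3%, and 3 splits are too few to judge the excess. Leaving out any 1 array lowered the called counts. Each omission leaves 1 array in a group and 1 residual degree of freedom, so the drop cannot be assigned to particular arrays. The share of calls that were higher was 54.5%, and it was 31% without normalization and 32.6% with median centring, under which the median log2 fold change of all genes was -0.10 against -0.01 in the main setting. Before normalization, 0 and 30 probes lay under the floor on mock arrays 1 and 2, and 848 and 175 on PSC medium arrays 1 and 2. Whether this difference in background shaped the calls made without quantile normalization was not tested.

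Among genes above the median level, 162 rose and 107 fell. The 15 largest increases ranged from 4.33-fold to 7.48-fold. After S100A2, INHBA and MMP1 came GP2, a glycoprotein of zymogen granule membranes (2.53 ± 0.17), and ANXA2P1, an annexin A2 pseudogene (2.47 ± 0.16). The annexin A2 gene itself, ANXA2, named after its values were seen, rose by 1.34 ± 0.23 (adjusted p = 0.0497), and the 2 near-identical copies are uncertain. ID1, an inhibitor of basic helix-loop-helix factors, rose by 2.30 ± 0.20, and H2BC17, a histone H2B gene whose sequence resembles its paralogs, by 2.28 ± 0.20. SQSTM1, the autophagy receptor p62, rose by 2.26 ± 0.16, and LAMP3, a lysosomal membrane protein gene, by 2.17 ± 0.18. The ERK phosphatase gene DUSP5 rose by 2.19 ± 0.17, the stress-induced transcription factor gene ATF3 by 2.17 ± 0.19 and the mTORC1 inhibitor gene DDIT4 by 2.15 ± 0.21. LRATD1 rose by 2.20 ± 0.17, the leukocyte receptor gene LILRA2 by 2.17 ± 0.16 and the endothelin-converting enzyme gene ECE2 by 2.11 ± 0.20.

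Among genes above the median level in at least 1 group, the 15 largest decreases ranged from 2.91-fold to 5.25-fold. CRISP2, a cysteine-rich secretory protein gene, had a log2 fold change of -2.39 ± 0.19, and CA8, a carbonic anhydrase-related gene, of -1.94 ± 0.16. APELA, which encodes a ligand of the apelin receptor, fell by 1.87 ± 0.20, and the leptin receptor gene LEPR by 1.65 ± 0.18. The calcium channel gene CACNA1A fell by 1.72 ± 0.16, the monocarboxylate transporter gene SLC16A12 by 1.66 ± 0.18 and the phospholipid flippase gene ATP8A1 by 1.64 ± 0.17. PROX1, a homeobox transcription factor gene of the developing pancreas, fell by 1.66 ± 0.16, and the WNT receptor gene FZD1 by 1.64 ± 0.15. The guanylate cyclase subunit gene GUCY1A1 fell by 1.59 ± 0.20. The remaining decreases were those of SPAG17 (-1.83 ± 0.15), HEPACAM2 (-1.69 ± 0.25) and TMEM170B (-1.54 ± 0.16). Of 34 other probes of the genes that the rule named and limma called, 29 had the same sign, 20 of them at an unadjusted p under 0.05, and of the 10 above the median level all had the same sign, 9 of them at an unadjusted p under 0.05. Probes of the same sign but close to 0 included those of SLC16A12 (-0.07), POLH (-0.09), LSS (-0.11) and SERPINE2 (0.08). A dim probe each of ECE2, CACNA1A and LEPR had the opposite sign, while another probe of ECE2 and 2 others of LEPR had the same sign.

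**Figure D1:**
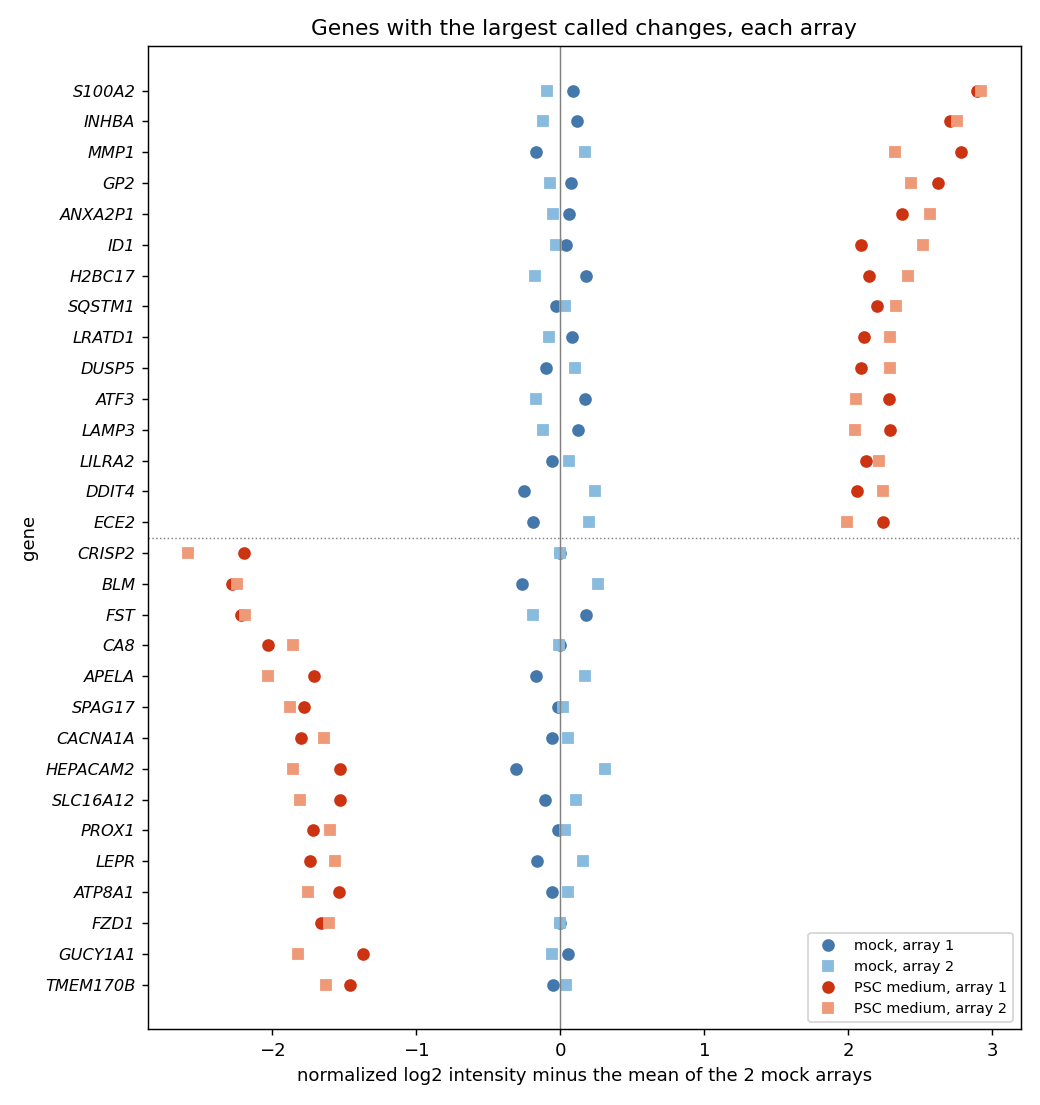
Normalized log2 intensity of each of the 4 arrays minus the mean of the 2 mock arrays (horizontal axis, log2) for the 15 genes with the largest increases and the 15 with the largest decreases (vertical axis), circles for array 1 and squares for array 2. These are the largest among called genes above the median level in at least 1 group whose groups did not overlap. The PSC medium arrays therefore lie apart from both mock arrays by selection. S100A2 lies at a mean of 2.90 and CRISP2 at -2.39.

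Genes of the ATF4 and amino acid response rose as a group with PSC medium. Of 40 measured members, 15 rose, 0 fell and 25 did not pass, with 27 higher and 1 lower adjusted over the list alone (median log2 fold change 0.85, camera adjusted p = 1.96e-16; adjusted p = 0.336 with an estimated correlation). CTH, an enzyme of cysteine synthesis, rose by 1.86 ± 0.16 (adjusted p = 0.0122), and PHGDH, the first enzyme of serine synthesis, by 1.61 ± 0.17 (adjusted p = 0.0185). ATF3 and DDIT4 were the other leading members. Further members, chosen after their values were seen, were the leucine transporter gene SLC7A5 (1.13 ± 0.16), the pseudokinase gene TRIB3 (1.06 ± 0.15), the glutathione-degrading enzyme gene CHAC1 (1.15 ± 0.17) and the alanyl-tRNA synthetase gene AARS1 (1.07 ± 0.16). ATF4 itself had a log2 fold change of 0.38 ± 0.20 (adjusted p = 0.312) and the asparagine synthetase gene ASNS of 0.79 ± 0.16 (adjusted p = 0.0663). The cystine transporter gene SLC7A11 had the opposite sign at -0.90 ± 0.17 (adjusted p = 0.0578).

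**Figure D2:**
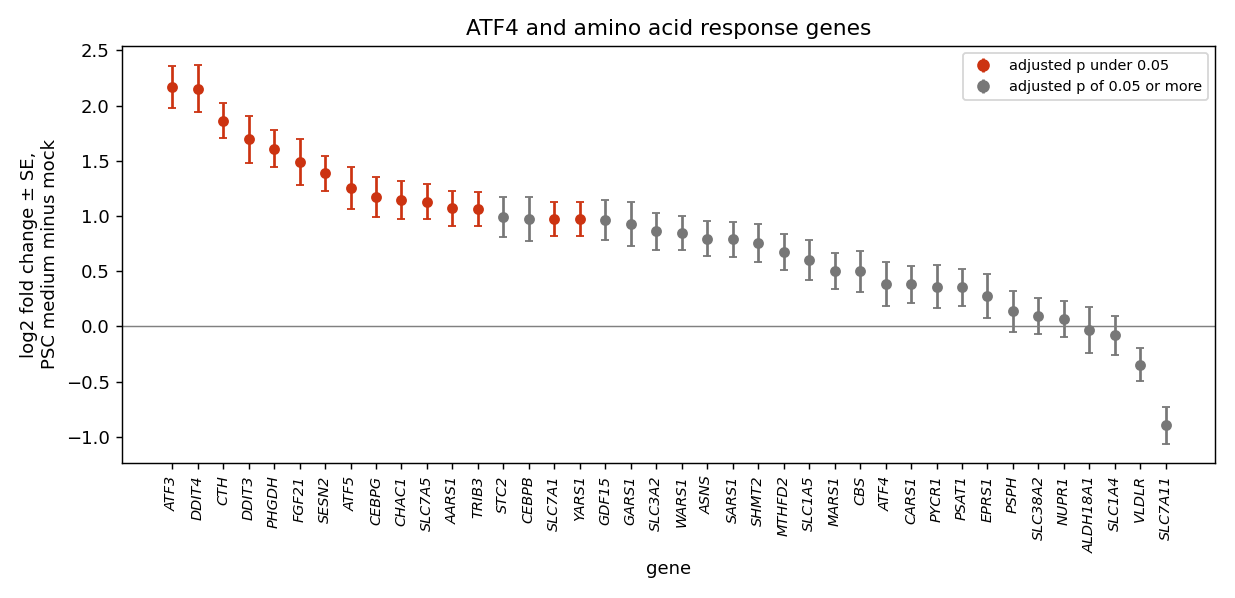
Log2 fold change, PSC medium minus mock, with its standard error (vertical axis, log2) for the 40 measured ATF4 and amino acid response genes (horizontal axis), red where the adjusted p is under 0.05. The 15 red genes all lie above 0, and SLC7A11 lies at -0.90.

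The unfolded protein response list had 1 of 33 members higher, DDIT3, a pro-apoptotic transcription factor gene (1.69 ± 0.21, adjusted p = 0.0288), and 0 lower, with 7 higher and 0 lower adjusted over the list alone. XBP1, a transcription factor gene of that response, had 0.79 ± 0.16 (adjusted p = 0.0655). The list did not pass (adjusted p = 0.575), and its median of -0.09 differed in sign from its mean of 0.07 and its test. Of 27 p53 targets, 3 rose and 1 fell, with 11 and 5 adjusted over the list alone (adjusted p = 0.0603). They were the stress-induced SESN2 (1.39 ± 0.16), the pro-apoptotic BBC3 (1.46 ± 0.19) and the death receptor gene TNFRSF10B (1.28 ± 0.19), with the DNA polymerase eta gene POLH at -0.96 ± 0.16. The p53 list was called higher in 6 of 18 alternative settings (adjusted p from 0.00175 to 0.386). Without its 2 members shared with the ATF4 list, SESN2 among them, its camera adjusted p was 0.201. Of 28 metallothionein and NRF2 genes, 2 rose and 1 fell, with 3 and 3 adjusted over the list alone (adjusted p = 0.135). Heme oxygenase gene HMOX1 rose by 1.03 ± 0.17, sulfiredoxin gene SRXN1 by 0.91 ± 0.15, and metallothionein gene MT1F fell by 1.06 ± 0.15.

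Immediate early and ERK feedback genes also rose as a group. Of 38 measured members, 8 rose, 0 fell and 30 did not pass, with 17 higher and 3 lower adjusted over the list alone (median 0.46, camera adjusted p = 2.98e-07; adjusted p = 0.336 with an estimated correlation). Beside DUSP5 and ATF3, the transcription factor gene KLF6 rose by 1.75 ± 0.17 (adjusted p = 0.0155) and PHLDA1 by 1.53 ± 0.17 (adjusted p = 0.0225). JUN (1.51 ± 0.17) and EGR1 (1.44 ± 0.21), chosen after their values were seen, rose too.

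The IL-6 family and STAT3 response list rose, with 2 of 33 members higher and 0 lower, and 4 and 0 adjusted over the list alone (median 0.22, camera adjusted p = 0.00153; adjusted p = 0.386 with an estimated correlation). They were IL6R, the IL-6 receptor gene (1.72 ± 0.15, adjusted p = 0.0131), and the transcription factor gene BATF3 (1.24 ± 0.15, adjusted p = 0.0288). The hypoxia and glycolysis list rose, with 3 of 40 members higher and 0 lower, and 9 and 3 adjusted over the list alone (median 0.20, camera adjusted p = 0.00375; adjusted p = 0.386 with an estimated correlation). The 3 members were DDIT4, the clock-related repressor gene BHLHE40 (1.46 ± 0.16) and the stress-responsive NDRG1 (1.27 ± 0.18), none of which is a glycolytic enzyme gene. Without the 2 members shared with the ATF4 list, DDIT4 among them, the hypoxia list's camera adjusted p was 0.0144. VEGFA, the vascular growth factor gene, had 0.90 ± 0.16 (adjusted p = 0.0567).

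The MYC and ribosome biogenesis list rose by its test, although 0 of 35 members passed alone, 0 passed adjusted over the list alone, and 6 were higher and 0 lower at an unadjusted p under 0.05 (median 0.19, camera adjusted p = 0.0135; adjusted p = 0.386 with an estimated correlation). Its leading members were RRP12 (0.78 ± 0.16, adjusted p = 0.0682) and NOC2L (0.70 ± 0.15, adjusted p = 0.0742), both of ribosome assembly, and MYC at 0.90 ± 0.20 (adjusted p = 0.0789). The DNA replication list rose likewise, with 0 of 41 members passing alone, 0 adjusted over the list alone, and 9 higher and 1 lower at an unadjusted p under 0.05 (median 0.22, camera adjusted p = 0.0135; adjusted p = 0.386 with an estimated correlation). MCM4, a helicase subunit gene, had 0.81 ± 0.19 (adjusted p = 0.0901). Without PSC medium array 1 the adjusted p was 0.112 for the MYC list and 0.108 for the replication list, and for the latter 0.0834 without mock array 1. The MYC list also missed the threshold once genes under the median level were left out (adjusted p = 0.0506). With fry the adjusted p was 0.0741 for the MYC list and 0.105 for the replication list. Of 37 mitosis genes and 37 cytoplasmic ribosomal protein genes, 0 passed in limma and 0 adjusted over the list alone, with 1 higher and 5 lower, and 0 higher and 1 lower, at an unadjusted p under 0.05 (both lists' adjusted p = 0.787). The ribosomal list's median of -0.00637 differed in sign from its mean of 0.00848 and its test. ASPM, a spindle protein gene, had -0.83 ± 0.16 (adjusted p = 0.0598), and RPL22 had -0.85 ± 0.16 (adjusted p = 0.0609). For 42 respiratory chain genes, 0 passed in limma and 0 adjusted over the list alone, with 2 higher and 4 lower at an unadjusted p under 0.05 (adjusted p = 0.759).

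Cholesterol and fatty acid synthesis genes fell as a group, with 1 of 31 members lower and 0 higher, and the same counts adjusted over the list alone (median -0.30, camera adjusted p = 0.0144; adjusted p = 0.386 with an estimated correlation). The member was LSS, lanosterol synthase (-1.31 ± 0.19, adjusted p = 0.0384). ELOVL6, a fatty acid elongase gene, had -0.70 ± 0.16 (adjusted p = 0.0814), and SREBF2, the transcription factor gene that controls cholesterol synthesis, had the opposite sign at 0.67 ± 0.17 (adjusted p = 0.0977). The list's adjusted p was 0.0993 without normalization, 0.0549 with median centring, 0.109 without mock array 2, 0.0537 without PSC medium array 1 and 0.0741 with fry.

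**Figure D3:**
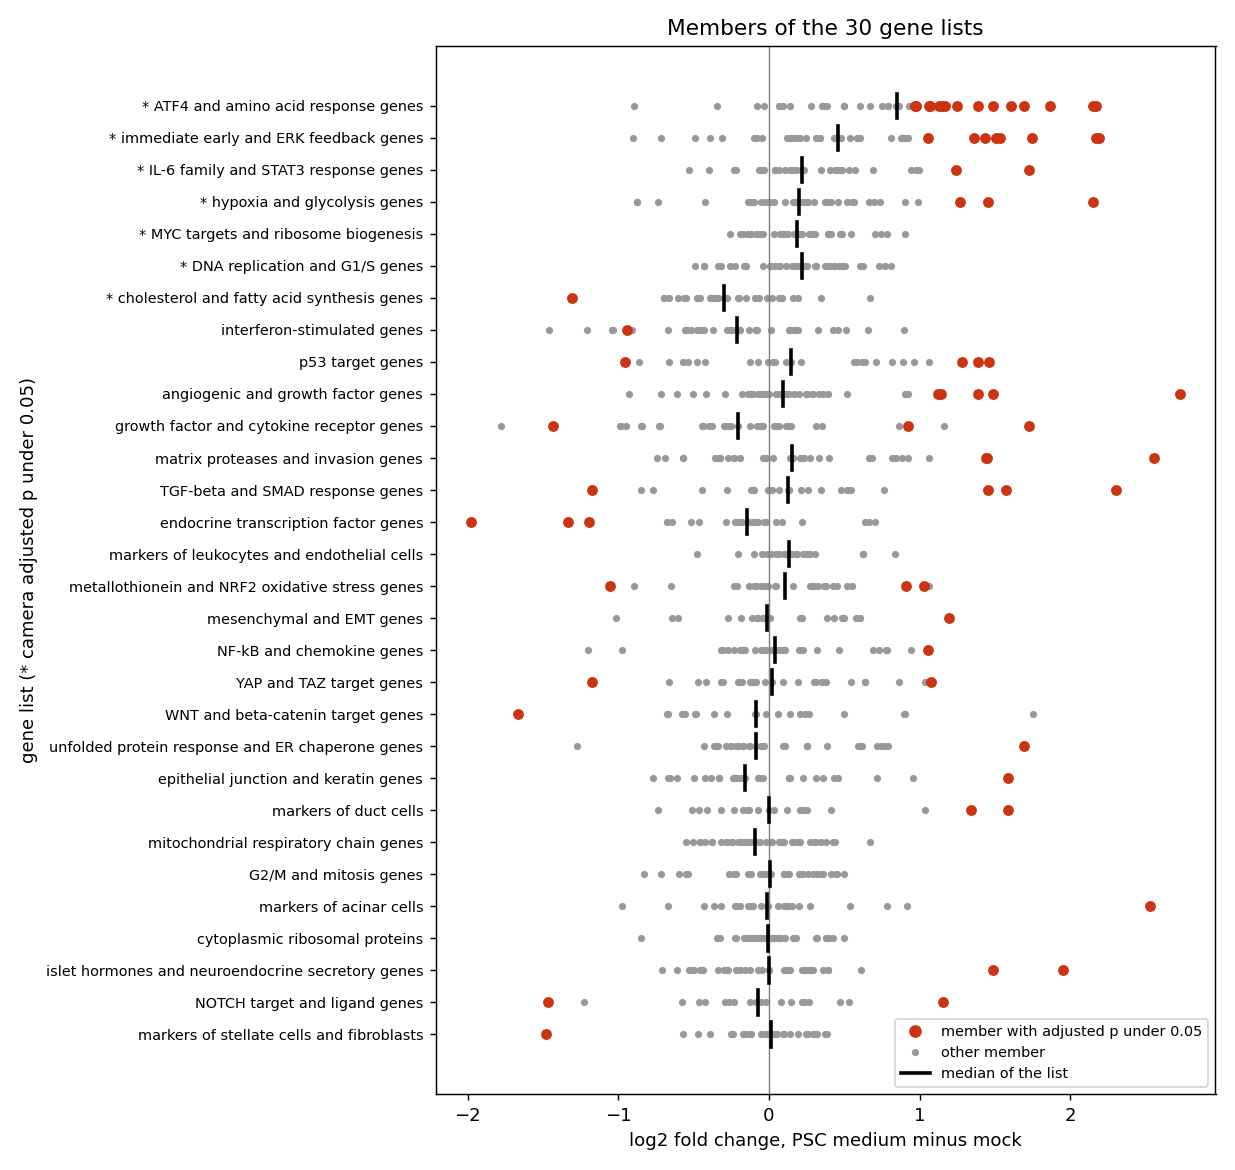
Log2 fold change, PSC medium minus mock (horizontal axis, log2), of every measured member of the 30 gene lists (vertical axis), ordered by the test, with members at an adjusted p under 0.05 in red and the list median as a black bar. The ATF4 and amino acid response list has the highest median, 0.85, and the cholesterol and fatty acid synthesis list the lowest, -0.30.

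Neither list of neuroendocrine genes passed as a group. Of 40 islet hormone and secretory genes, 2 rose and 0 fell, with 2 and 0 adjusted over the list alone (adjusted p = 0.787; the median of -0.000375 and the mean of 0.03 differed in sign). VGF, the precursor of secreted neuropeptides, rose by 1.95 ± 0.16 (adjusted p = 0.0122), and CALCB, a calcitonin gene-related peptide gene, by 1.49 ± 0.17 (adjusted p = 0.0245). SST had -0.45 ± 0.18 (adjusted p = 0.216). Of 27 endocrine transcription factor genes, 3 fell and 0 rose, with 4 lower and 2 higher adjusted over the list alone (adjusted p = 0.127). A negative log2 fold change was found for 21 of the 27 and a positive one for 6 (mean -0.238). NKX2-2, required for islet cell differentiation, fell from 9.91 ± 0.23 to 7.93 ± 0.18 (-1.98 ± 0.19, adjusted p = 0.0158), ONECUT2 by 1.33 ± 0.16 (adjusted p = 0.0251) and ST18 by 1.20 ± 0.17 (adjusted p = 0.0384). A second probe of ONECUT2, also above the median gene level, had a log2 fold change of -0.17 and did not pass.

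Among 40 angiogenic and growth factor genes, 5 rose and 0 fell, with 7 and 1 adjusted over the list alone (adjusted p = 0.0603). Beside INHBA they were the insulin-like growth factor gene IGF2 (1.39 ± 0.17), the metabolic hormone gene FGF21 (1.49 ± 0.21), the IGF-binding protein gene IGFBP2 (1.14 ± 0.17) and IGFBP5 (1.12 ± 0.18), the last named after its values were seen. This list was called higher in 5 of 18 alternative settings (adjusted p from 0.00143 to 0.697). Of 37 receptor genes, 2 rose and 1 fell, with 3 and 8 adjusted over the list alone (adjusted p = 0.0787). IL6R rose, the ephrin receptor gene EPHA2 rose by 0.92 ± 0.16, and the insulin receptor gene INSR fell by 1.44 ± 0.19. Of 35 matrix protease and invasion genes, 3 rose and 0 fell, with 10 and 4 adjusted over the list alone (adjusted p = 0.0787). Beside MMP1, the stromelysin gene MMP10 rose by 1.45 ± 0.22 (adjusted p = 0.0412) and the protease inhibitor gene SERPINE2 by 1.44 ± 0.20 (adjusted p = 0.0347).

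Of 26 TGF-beta and SMAD response genes, 3 rose and 1 fell, with 5 and 3 adjusted over the list alone (adjusted p = 0.1). ID1, ID3 (1.58 ± 0.15) and BHLHE40 rose, and the matricellular protein gene CCN2 fell by 1.18 ± 0.15 (adjusted p = 0.031). The list was called higher in 3 of 18 alternative settings (adjusted p from 0.000856 to 0.416). Of 22 mesenchymal genes, 1 rose, the matrix glycoprotein gene TNC (1.19 ± 0.19, adjusted p = 0.0452), and 0 fell, with 1 and 1 adjusted over the list alone (adjusted p = 0.395). The list's median of -0.02 differed in sign from its mean of 0.09 and its test. Of 29 epithelial junction and keratin genes, 1 rose, KRT19, a keratin of duct epithelium (1.59 ± 0.20, adjusted p = 0.0299), and 0 fell, with 2 and 2 adjusted over the list alone (adjusted p = 0.759).

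Of 41 interferon-stimulated genes, 0 rose and 1 fell, with 1 and 2 adjusted over the list alone (median -0.21, adjusted p = 0.0603). Without normalization the list was called lower (mean -0.41, adjusted p = 0.0166), as it was with median centring (-0.54, adjusted p = 0.0445) and with fry (adjusted p = 0.0453), and over 18 alternative settings the adjusted p ranged from 0.0166 to 0.82. Only 24.4% of the list's genes lay above the median gene level. Before normalization more probes lay under the floor on the PSC medium arrays than on the mock arrays. The member that fell was EPSTI1 at -0.94 ± 0.16, which was 0.09 when its probes were averaged. Of 31 NF-kB and chemokine genes, 1 rose, the early response gene IER3 (1.05 ± 0.15), and 0 fell, with 3 and 1 adjusted over the list alone (adjusted p = 0.521). Of 27 YAP and TAZ targets, GADD45B, a stress-inducible gene, rose by 1.07 ± 0.17 and CCN2 fell, with 1 and 2 adjusted over the list alone (adjusted p = 0.573). Of 21 WNT targets, 0 rose and 1 fell, PROX1, with 2 and 3 adjusted over the list alone (adjusted p = 0.575). Of 20 NOTCH genes, the target HEY1 rose by 1.16 ± 0.18 and LFNG, a glycosyltransferase acting on NOTCH, fell by 1.47 ± 0.21, with 1 and 1 adjusted over the list alone (adjusted p = 0.798). A dim probe each of EPSTI1 and LFNG had the opposite sign, while another probe of EPSTI1 had the same sign.

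No list of markers of other cell types passed as a group. Of 30 stellate cell and fibroblast markers, 0 rose and 1 fell, with 0 and 1 adjusted over the list alone (adjusted p = 0.885), the member being the intermediate filament gene DES (-1.48 ± 0.17), dim in both groups. Of 26 acinar markers, GP2 rose and 0 fell, with 2 and 1 adjusted over the list alone (adjusted p = 0.787; the median of -0.01 and the mean of 0.08 differed in sign). Of 21 duct markers, KRT19 and the trefoil factor gene TFF1 (1.34 ± 0.20) rose and 0 fell, with 2 and 0 adjusted over the list alone (adjusted p = 0.759; the median of -0.00197 and the mean of 0.11 differed in sign). Of 25 leukocyte and endothelial markers, 0 passed in limma and 0 adjusted over the list alone, with 1 higher and 1 lower at an unadjusted p under 0.05 (adjusted p = 0.135).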

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

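Probes with no gene name here were outside the comparison of genes, and some of them differed between the groups. With every probe tested on its own in limma, 12 of 2371 unnamed probes were higher with PSC medium and 5 were lower. These were 0.717% of the unnamed probes, against 0.626% of the 25893 named probes. The unnamed probe with the largest change was at the floor on both mock arrays and had a mean of 9.40 on the PSC medium arrays.

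Among the 409 called genes, 16 had a value at the floor, 5 of them higher and 11 lower with PSC medium. Background subtraction to values near 0 is a candidate source of these calls, by a test planned before its result was seen. With 50 added to each intensity, 1 of the 16 stayed past the threshold, PELATON, chosen here after its values were seen (log2 fold change 1.16, adjusted p = 0.00186). A real change in these dim genes remains open for the other 15, since an added constant shrinks any change at such intensities.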

How the results depend on the processing

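The number of called genes depended on the processing, and the cause was not tested unless stated. The main setting had 223 higher and 186 lower (205 and 163 at least 2-fold). Values without normalization gave 35 and 78, median centring 30 and 62, and cyclic loess 112 and 72, all at least 2-fold. These were not all subsets of the 409 main calls. The main calls held 53 of the 113 calls without normalization, 51 of 92 with median centring and 181 of 184 with cyclic loess. The mean of a gene's probes gave 60 and 33, and every probe on its own 109 and 70, again all at least 2-fold. Leaving out genes under the 25th percentile of level gave 1278 and 1533 calls with 10 lists higher, leaving out those under the median 824 and 974, and adding 50 to each intensity 883 and 1153. A trended and robust variance prior called 1560 and 1838 (246 at least 2-fold lower). Its median prior degrees of freedom were infinite, so its p-values rest on a spread pooled over genes, hardly on a gene's own arrays. No variance moderation gave 3 and 0 (1 and 0 at least 2-fold, with 2799 at an unadjusted p under 0.05). A looser threshold, an adjusted p under 0.1, gave by construction 691 and 855 with 3 lists lower, and an unadjusted p under 0.05 gave 1879 and 2420 (328 and 279 at least 2-fold). Chosen after seeing the data, leaving out genes with a floor value gave 425 and 477, and doing so with the trended and robust prior 1554 and 1833 (249 at least 2-fold lower). Genes with a floor value widening the variance prior were thus not the whole cause of the difference between priors, since the standard prior then called 902 genes against 3387.

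With each array left out in turn, which leaves 1 residual degree of freedom and assumes that the lone array varies like the other group, 0 to 21 genes were higher and 0 to 15 lower (0 to 21 and 0 to 15 at least 2-fold). The lowest counts came without PSC medium array 1. Under the same omissions 4 to 8 lists were higher and 0 to 1 lower. The real split of the 4 arrays called 409 genes and the highest other split 1, so 1 of 3 splits gave as many, and 3 splits are too few for a share under 0.05; this test was chosen after the result was seen.

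The replicate numbers were taken only as names, not as pairs: there were 2 pairs, and the correlation of same-numbered deviations was 0.0686. A replicate block gave 59 genes higher and 25 lower, all at least 2-fold, and 80 of the 409 calls were shared. No list call changed with it.

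The 85 named genes that passed had the same direction in each of these settings that tested them, except EPSTI1 with the mean of its probes (0.08962, by the inclusion of dimmer probes). Of the 85, 23 passed without normalization, 24 with median centring and 60 with cyclic loess. All 85 passed with 50 added, and 85 with the trended and robust prior. That prior uses a spread pooled over genes, so its 85 do not show replication between arrays. Of the 85, 3 passed without mock array 1, 1 without mock array 2, and 0 without either PSC medium array. Lists called were 6 higher and 1 lower, and 0 higher and 0 lower with an estimated correlation, where the smallest adjusted p was 0.336. The estimated correlations of the called lists ran from -0.017 to 0.017, near the preset 0.01. That test takes the 2 residual degrees of freedom, so the loss of calls does not show high correlation between genes. Leaving out members shared with the ATF4 list, chosen after seeing the data, gave 6 lists higher and 1 lower. With fry, 5 lists were higher and 3 lower. Under fry the adjusted p was 0.0741 for the MYC and the cholesterol lists and 0.105 for the replication list, over a range in which the ATF4 list had 0.0328. Lists called in some settings but not in the main one were interferon (3 of 18), p53 (6), angiogenic (5), TGF-beta (3), matrix protease (2; adjusted p from 0.0203 to 0.739), NRF2 (2; 0.04 to 0.697), WNT (1; 0.0453 to 0.739) and receptor genes (1; 0.0453 to 0.466). Without normalization and with median centring the 1 lower list was the interferon list in place of the cholesterol list. Signal over background limits the dim genes, whose fold changes move with the floor.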

Other observations

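The S100 and annexin genes, which encode calcium-binding proteins and were not among the fixed lists as families, and the frizzled receptors were examined after their values were seen. Of 21 measured S100 genes, 4 rose with PSC medium and 0 fell: S100A2 (2.90 ± 0.16 SE, n = 2 per group), S100A11 (2.04 ± 0.19, limma adjusted p = 0.0145), S100A10 (1.96 ± 0.17, adjusted p = 0.0131) and S100A14 (1.73 ± 0.19, adjusted p = 0.0228). S100A10 encodes the partner of annexin A2, whose gene ANXA2 rose by 1.34 ± 0.23, and ANXA3 rose by 1.35 ± 0.16 (adjusted p = 0.0251). Among 261 groups of at least 10 genes that share the start of their symbol, the S100 group had a camera adjusted p of 0.0459 with S100PBP, which encodes an S100P-binding protein, and of 0.0603 without it. With an estimated correlation its p, with S100PBP and not adjusted over the groups, was 0.0844. Without S100PBP, its direction was up under all 5 scalings, and its adjusted p ranged from 0.014 with 50 added to 0.07 without normalization. The dual-specificity phosphatases (DUSP) had an adjusted p of 0.0675, and ranked above the S100 group without normalization and with median centring. The annexin group had 0.107. None of the 3 groups passed under all 5 scalings.

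Of 10 frizzled genes, receptors of WNT proteins, FZD1 (-1.64 ± 0.15, adjusted p = 0.015) and FZD4 (-1.30 ± 0.17, adjusted p = 0.0323) fell and 0 rose, while FZD3 had -0.997 ± 0.18 (adjusted p = 0.0567). The family as a whole did not pass (adjusted p = 0.446).

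The tests of endoplasmic reticulum stress and of carried-over RNA below, the latter in place of a void comparison of intensities between probes, were chosen after values they use were seen, and the test of signal level before. The ATF4 and amino acid response list rose with a median of 0.85. Normalization that depends on signal level is argued against, since 0 of 10000 random lists matched on level had a median as high, and their medians ranged from -0.28 to 0.23. Endoplasmic reticulum stress that raises chaperones as strongly is argued against too. The unfolded protein response list without shared members had a median of -0.129 (SD 0.458 over 31 genes). The median was 0.82 for 8 aminoacyl-tRNA synthetases (0.279 to 1.07) and -0.13 for 10 chaperones (-0.363 to 0.766), so the ranges overlapped. The 2 shared members left out were ATF4 and DDIT3, of which DDIT3 rose by 1.69. Stress that does not raise chaperones was not tested and stays open. A shortage of amino acids in conditioned medium, or a secreted factor, may be the reason, and no array separates these.

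INHBA and MMP1, which fibroblasts and stellate cells also transcribe, rose by 2.73 and 2.55. Stellate cell RNA carried over with the medium could raise such transcripts, and would bring abundant matrix transcripts with it. Among COL1A2, COL3A1, COL6A3, LUM, DCN, FN1, POSTN and VIM, all dim in mock cells, the median change was 0.175 (SD 0.266), 0 of 8 passed in limma and 0 had an unadjusted p under 0.05, which argues against it. No array of stellate cells shows that these dim probes respond, which limits the argument. Other transcripts that stellate cells also make were chosen after their values were seen. STC1 rose by 1.85 (adjusted p = 0.0122), SERPINE2 by 1.44 (adjusted p = 0.0347) and TNC by 1.19 (adjusted p = 0.0452). COL1A1 (0.29), SPARC (0.38), TIMP1 (0.15), COL6A1 (-0.39), ACTA2 (-0.12) and TAGLN (-0.47) did not pass in limma. A response of the QGP-1 cells to the medium is a hypothesis that stays open.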
